A study of Mus musculus with 6 samples.

How the data were processed

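The series measured messenger RNA by sequencing in primary alveolar epithelial cells, the cells that line the gas-exchange surface of the lung, taken from C57BL/6 mice. Cultures received OMVs or PBS (phosphate-buffered saline, the vehicle) for 24 h, with 3 libraries per group. The labels do not spell out OMVs. The usual reading is outer membrane vesicles shed by Gram-negative bacteria, and neither a bacterial source nor a dose is given in the sources used here. Groups and replicate numbers were taken from the sample titles. Nothing says that the replicates came from separate animals or cultures, so every p-value measures only the spread between these samples, which may be technical.

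Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 RNA-seq kit. HISAT2, with no version, is the aligner named in the submitters' processing notes. The genome build, the gene annotation, the counting tool and the strand setting are not given in the sources used here. The authors deposited one table of counts per library, with whole numbers of reads per gene symbol, and one table of FPKM (fragment counts scaled by gene length and library total) for the series.

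The count tables used here held 8526 genes each. The lowest count in any OMVs library was 642, whereas PBS counts went down to 11. The lowest OMVs mean was 13.92 CPM (counts scaled to a common library total) and the lowest PBS mean was 0.35 CPM. Genes with few reads in the OMVs libraries were therefore not analysed here, and a gene could enter with a low PBS value but not with a low OMVs value. Falls are bounded by this and the largest falls cannot be seen, while rises are not. A list member outside the tables has no value here, and its absence says nothing about its expression. The FPKM table held 8788 genes, the same 8526 and 262 others. The symbol of each of these 262 genes is the beginning of another symbol in the count tables.

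For every gene and library, the ratio of count to FPKM separated into a whole-number gene length (within a tolerance of 0.01) and a library total. These totals, 53448094, 53267346 and 54819378 reads for PBS replicates 1 to 3 and 52456372, 50330663 and 53225584 for OMVs replicates 1 to 3, were used as library sizes. The tables themselves summed to between 48669279 and 52893349, or 96.4% to 96.7% of the totals. Chi-square per degree of freedom over all genes lay between 5.31 and 29.41 for pairs within a group, above the value of 1 that counting noise alone gives, so no library was a copy of another. Between groups it lay between 566.65 and 600.75.

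Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group (which removed no gene), TMM scaling (factors 0.988 to 1.013), robust dispersion and the quasi-likelihood F test of OMVs against PBS, two-sided, without a replicate block. P-values were adjusted by the Benjamini-Hochberg method over all 8526 genes and called at 0.05. The standard error of a log2 fold change was derived from its F statistic. CPM values are TMM-scaled. Gene lists, 23 for pathways and cell states and 12 for cell types, were fixed before the data were examined. Lists with at least 5 measured members were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, which compares a list with the other measured genes. The camera p was adjusted over the 26 lists tested. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were alternatives. Principal components were taken from log2 CPM with a prior count of 2.

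The genes named were also chosen by a rule fixed before the data were examined. They were the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups, up to 2 rises and 2 falls per list, and 9 fixed genes (Sftpc, Ager, Epcam, Cdh1, Ptprc, Col1a1, Tlr4, Tlr2 and Cd14). Predicted genes, pseudogenes, ribosomal protein genes, mitochondrial genes and receptor or immunoglobulin segments were left out of the largest changes. The rule gave 109 genes, of which the report names a part. Exon overlap was checked in the GENCODE M21 annotation of GRCm38. No coordinates are given because the build behind the counts is not known. Of the named genes only Cfb shared over 25% of its exon bases with another gene, and Clec7a, annotated as a polymorphic pseudogene, was not assessed. Reads of near-identical copies may be split in unknown ways, which makes Cfb, Lyz1, Scd1, Scd2 and the H2 genes uncertain.

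The gene test was checked on simulated counts for the same 8526 genes and libraries, in 3 runs with 200 changed genes each. It recovered 84.7% of the genes changed 1.25-fold, 100% of those changed 1.5-fold, 99.3% at 2-fold and 100% at 4-fold, with 5.1% false calls. The simulation changed few genes, in equal numbers up and down, and held no gene length trend. In the data 5561 genes were called and the libraries differed along gene length, so these rates may not carry over. Alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling, the DESeq2 Wald test, limma-voom, other filters and thresholds, a replicate block, leaving out each library, leaving out leukocyte marker genes, and limma on log2(FPKM + 1) or log2(FPKM + 0.1). Alternatives chosen after seeing the data were table sums as library sizes, removal of the 50 most abundant genes, a subset of genes by mean level, a subset by PBS level, and removal of a gene length trend. Tables were read with Python 3.11.15 and pandas 2.3.3.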

Results

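RNA sequencing was used to ask how OMVs change gene expression in primary mouse alveolar epithelial cells. The series holds 6 libraries, 3 from cells given PBS and 3 from cells given OMVs, all at 24 h. Library totals ranged from 50330663 to 54819378 reads, so that even the least abundant measured gene had at least 11 counts in each library. Values below are mean CPM ± SD (n = 3) and log2 fold changes of OMVs over PBS ± SE. Genes with few reads in the OMVs libraries were not analysed here (lowest OMVs mean, 13.92 CPM), so rises from a very low PBS level are included and comparable falls are not. A measured gene with a PBS mean under 13.92 CPM could enter only as a rise. The counts, medians and camera p-values of lists that hold such genes are therefore biased towards rises.

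OMVs changed most of the measured transcriptome. Of 8526 genes, 5561 (65.2%) differed between the groups at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 2793 of them higher and 2768 lower with OMVs. TMM scaling centres the log2 fold changes (median 0.003). The near-even split is therefore in part set by the scaling, and the direction of the smallest changes depends on it. Most changes were small. At least 2-fold changes were seen in 689 genes (455 risen, 234 fallen), and at least 8-fold changes in 134 risen and 2 fallen genes. The surplus of large rises stands beside the absence of genes low in the OMVs libraries. For 5322 genes the geometric mean of the PBS and OMVs levels was at least 39.4 CPM, so an 8-fold fall would still have been measured. Of these, 1682 rose and 1937 fell, and 156 rose and 177 fell by at least 2-fold. Among the 2000 genes whose PBS level was at least 8 times the lowest OMVs mean, a choice by 1 group that favours falls, 563 rose and 983 fell. Both subsets were chosen after seeing the data. Refitted with TMM factors from their own genes, which centres the fold changes on those genes, the first gave 1815 risen and 1791 fallen and the second 786 risen and 774 fallen. The first principal component held 97.1% of the variance and separated the groups, and the second held 1.4%. The 3 OMVs libraries did not overlap the 3 PBS libraries in 5907 genes (69.3%, against 10% by chance). The biological coefficient of variation was 4.9%.

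**Figure D1:**
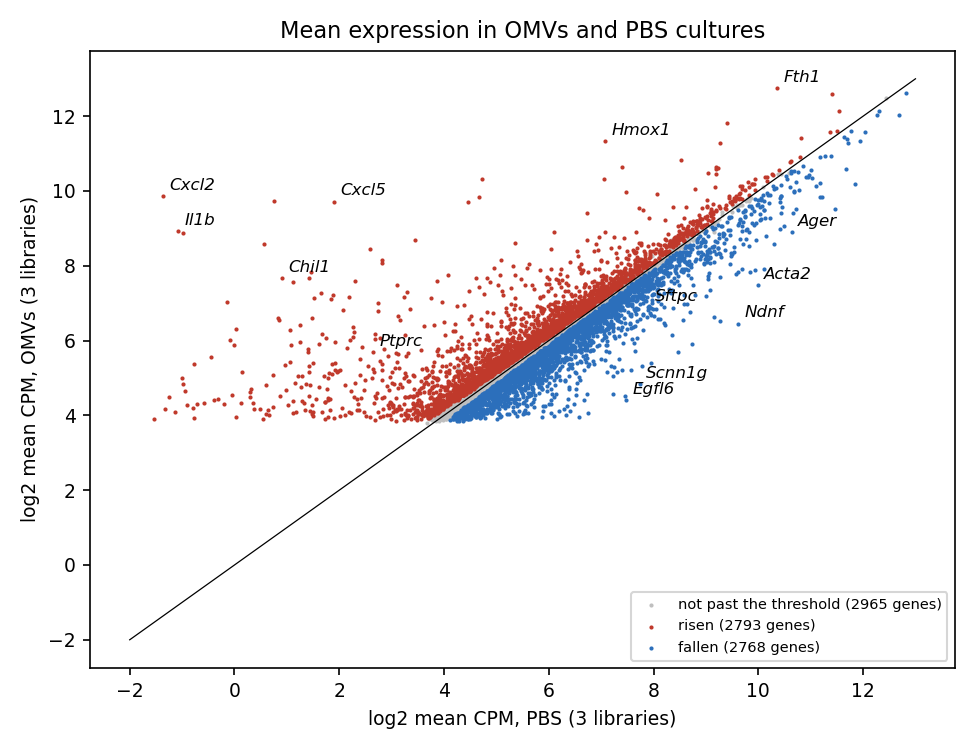
Mean expression of 8526 genes with PBS (x axis) and OMVs (y axis), as log2 CPM over 3 libraries each. Red points are the 2793 risen genes, blue points the 2768 fallen genes and grey points the rest. The line marks equal expression. The lower edge of the points on the y axis is the lowest OMVs mean, 13.92 CPM, and points left of it in PBS reach 0.35 CPM.

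Cytokine and chemokine genes showed the largest rises. Of the 32 genes in the list 21 were measured, 19 rose and 2 fell, with a median log2 fold change of 5.76 (camera adjusted p = 1.8e-103). Cxcl2, a neutrophil-attracting chemokine, went from 0.387 ± 0.118 CPM with PBS to 928 ± 39.5 CPM with OMVs, a log2 fold change of 11.21 ± 0.09 (edgeR adjusted p = 1.49e-19). Il1b and Il1a, which encode the interleukin-1 cytokines, rose by 9.98 ± 0.07 and 9.85 ± 0.14. Cxcl3, Cxcl1 and Cxcl5, chemokines of the same family, rose by 8.96 ± 0.06, 8.01 ± 0.07 and 7.80 ± 0.05. Ccl22, a chemokine for T cells, rose by 7.16 ± 0.11. Cx3cl1 (-0.98 ± 0.06) and Csf1 (-0.30 ± 0.03) were the 2 that fell. Cxcl2, Il1b, Il1a, Cxcl3, Cxcl1, Cxcl5, Ccl22 and many other members had PBS means under the lowest OMVs mean of 13.92 CPM. They could enter only as rises, so the count, median and camera p of this list are biased towards rises. The members with higher PBS means, which could have fallen, were Cx3cl1, Csf1, Cxcl16, Il11 and Lif. These ran from Cx3cl1 (-0.98 ± 0.06) to Lif (1.67 ± 0.03). Pan-leukocyte markers rose in the same libraries, with a median of 2.86.

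Genes of innate immune signalling rose with them. NF-kappaB targets and feedback inhibitors rose in 21 of 23 measured members and fell in 1 (median 1.49, camera adjusted p = 9.4e-21). Among them Cd83, a surface protein of activated immune cells, rose by 4.74 ± 0.22, and Irak3, an inhibitor of Toll-like receptor signalling, by 4.21 ± 0.10, while Icam1, an adhesion molecule, fell from 965 ± 13.4 to 542 ± 3.71 CPM (-0.83 ± 0.03). Cd83, Irak3, Traf1 and Zc3h12a had PBS means under the lowest OMVs mean of 13.92 CPM and could enter only as rises. Members with higher PBS means ran from Icam1 (-0.83 ± 0.03) to Nfkbiz (3.07 ± 0.07). Interferon-stimulated genes rose in 28 of 29 measured members of 43, with none fallen (median 2.49, camera adjusted p = 8.5e-34), led by Zbp1, a sensor of Z-form nucleic acids (5.80 ± 0.29), and Ifi44 (5.75 ± 0.15). Zbp1, Ifi44 and many other members had PBS means under the lowest OMVs mean of 13.92 CPM, so they could enter only as rises. Members with higher PBS means, which could have fallen, ran from Ifit2, not called (-0.06 ± 0.08), to Bst2 (2.49 ± 0.05). The 5 measured members of the inflammasome and pyroptosis list of 15 all rose (median 3.51, camera adjusted p = 3.4e-16), among them Nlrp3, the sensor protein of an inflammasome (6.15 ± 0.16). Nlrp3, Il1b, Naip2 and Gsdmd had PBS means under the lowest OMVs mean of 13.92 CPM, so they could enter only as rises. Ninj1, at 42.9 CPM with PBS, could have fallen and rose by 0.73 ± 0.06. Il18, on this list and the cytokine list, was held in the FPKM table alone, at under 1 FPKM. It did not rise (0.442 ± 0.1 FPKM with PBS and 0.373 ± 0.122 with OMVs, overlapping). Secreted antimicrobial and acute-phase genes rose in 11 of 12 measured members of 28 (median 2.65, camera adjusted p = 2.8e-32), led by Chil1, a chitinase-like protein (6.74 ± 0.08), and Cfb, complement factor B (6.27 ± 0.11). Chil1, Cfb, Lcn2, Ltf, Hp and Chil3 had PBS means under 13.92 CPM and could enter only as rises. Lyz1, a lysozyme, fell slightly (-0.24 ± 0.08), a call lost without PBS replicate 3, OMVs replicate 2 or OMVs replicate 3. The rise in pan-leukocyte markers, with a median of 2.86, moved with each of these lists.

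Receptors for bacterial products rose by different amounts. Cd14, the co-receptor for lipopolysaccharide, rose 13.2-fold, from 14.7 ± 1.13 to 194 ± 4.47 CPM (3.73 ± 0.06). Tlr2, the receptor for bacterial lipoproteins, rose 7.51-fold (2.91 ± 0.07), and Tlr4, the receptor for lipopolysaccharide, rose 1.81-fold (0.86 ± 0.07). Tlr2 had a PBS mean of 7.24 CPM, under the lowest OMVs mean of 13.92 CPM, and could enter only as a rise. Of the 15 measured members of the sensing list 9 rose and 1, Ripk2 (-0.17 ± 0.06), fell, with a median of 0.20 (camera adjusted p = 0.0045, and adjusted p = 0.24 with an estimated correlation). Ripk2 lost its call without PBS replicate 3 or OMVs replicate 1. In the MHC class I list 15 of 18 measured members rose and 3 fell (median 0.60, camera adjusted p = 0.0015, and adjusted p = 0.21 with an estimated correlation). Nlrc5, a transcriptional activator of these genes, rose by 2.66 ± 0.13 and B2m, the shared light chain, by 1.69 ± 0.04, while the chaperones Calr and Pdia3 each fell (-0.27 ± 0.03). Nlrc5, at 2.72 CPM with PBS, could enter only as a rise. In MHC class II, 3 members were measured and the list was not tested. H2-Ab1 (-1.27 ± 0.09) and Cd74, the invariant chain (-0.87 ± 0.03), fell, and Ctss, a protease that processes it, rose (1.59 ± 0.05). These changes also stood beside the rise of pan-leukocyte markers (median 2.86).

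Genes of alveolar type 1 cells, the thin cells across which gas is exchanged, fell as a group. Of 20 measured members 18 fell and 2 rose (median -1.48, camera adjusted p = 4.9e-23). Ager, a membrane receptor abundant in these cells, fell 3.32-fold, from 1596 ± 34.5 to 480.5 ± 5.69 CPM (-1.73 ± 0.03). Col4a3 and Col4a4, basement membrane collagens, fell by -2.76 ± 0.08 and -2.84 ± 0.05 on the log2 scale. Pdpn, also called podoplanin, went the other way (1.55 ± 0.04), as did Lmo7 (0.35 ± 0.03). Fibroblast and smooth muscle markers fell in the same libraries (medians -0.92 and -1.78), and pan-leukocyte markers rose (median 2.86).

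Genes of alveolar type 2 cells, which make surfactant, moved both ways. Of 19 measured members 8 rose and 10 fell. The median log2 fold change was -0.24, the mean was 0.20 and camera's direction was down (adjusted p = 0.66). Sftpc, which encodes surfactant protein C, fell from 240 ± 14.3 to 120 ± 3.25 CPM (edgeR adjusted p = 2.05e-11). Lpcat1, an enzyme of surfactant lipid synthesis, and Scd1, a fatty acid desaturase, fell by -1.28 ± 0.04 and -1.24 ± 0.03 on the log2 scale, whereas Chil1 (6.74 ± 0.08) and Cebpa, a transcription factor (1.24 ± 0.06), rose. Hc, a member of this list held in the FPKM table alone, fell from 3.006 ± 0.367 FPKM with PBS to 0.61 ± 0.173 with OMVs. In the subset of genes with a geometric mean of at least 39.4 CPM the type 2 list had a median of -0.83 and passed the test (adjusted p = 0.00528). The list for the transitional state between type 2 and type 1 cells held 10 risen and 12 fallen of 23 measured genes, with a median of -0.12, a mean of 0.35 and an upward direction in camera (adjusted p = 0.058, and adjusted p = 0.57 with an estimated correlation). Without OMVs replicate 3 its adjusted p was 0.0432, and in the subset by mean level its median was -0.10 (adjusted p = 0.0165), both upward in camera. Gdf15, a stress-induced cytokine, rose by 4.38 ± 0.06 and Ndrg1 by 2.11 ± 0.06, and Hbegf, a growth factor, fell (-1.02 ± 0.04), as did the integrin gene Itgb6 (-0.65 ± 0.05). Pan-leukocyte markers rose (median 2.86) and fibroblast and smooth muscle markers fell (medians -0.92 and -1.78) in the same libraries.

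Epithelial junction genes fell by modest amounts. Of 25 measured members 23 fell and 1 rose (median -0.35, camera adjusted p = 0.00029). Cldn18, a tight junction claudin, went from 2812 ± 121 to 737 ± 18.7 CPM (-1.93 ± 0.04), and Jup, which encodes plakoglobin, fell (-0.93 ± 0.03), while Tjp3, a tight junction scaffold, rose (1.45 ± 0.06). Cdh1, which encodes E-cadherin, fell from 1759 ± 5.13 to 1051 ± 28.3 CPM (-0.74 ± 0.03), and Epcam, an epithelial adhesion gene, fell slightly (-0.20 ± 0.04). Ion and water transport genes included 8 fallen and 4 risen of 14 measured (median -0.21, camera adjusted p = 0.00089). Scnn1g, a subunit of the epithelial sodium channel, was 7.45-fold lower (-2.90 ± 0.04) and Aqp5, a water channel, 3.33-fold lower (-1.74 ± 0.04). Cftr, a chloride channel, rose from 7.98 ± 0.127 to 20.2 ± 1.39 CPM (1.34 ± 0.08), and Nedd4l, a ubiquitin ligase, rose as well (0.66 ± 0.04). Pan-leukocyte markers rose in the same libraries (median 2.86).

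**Figure D2:**
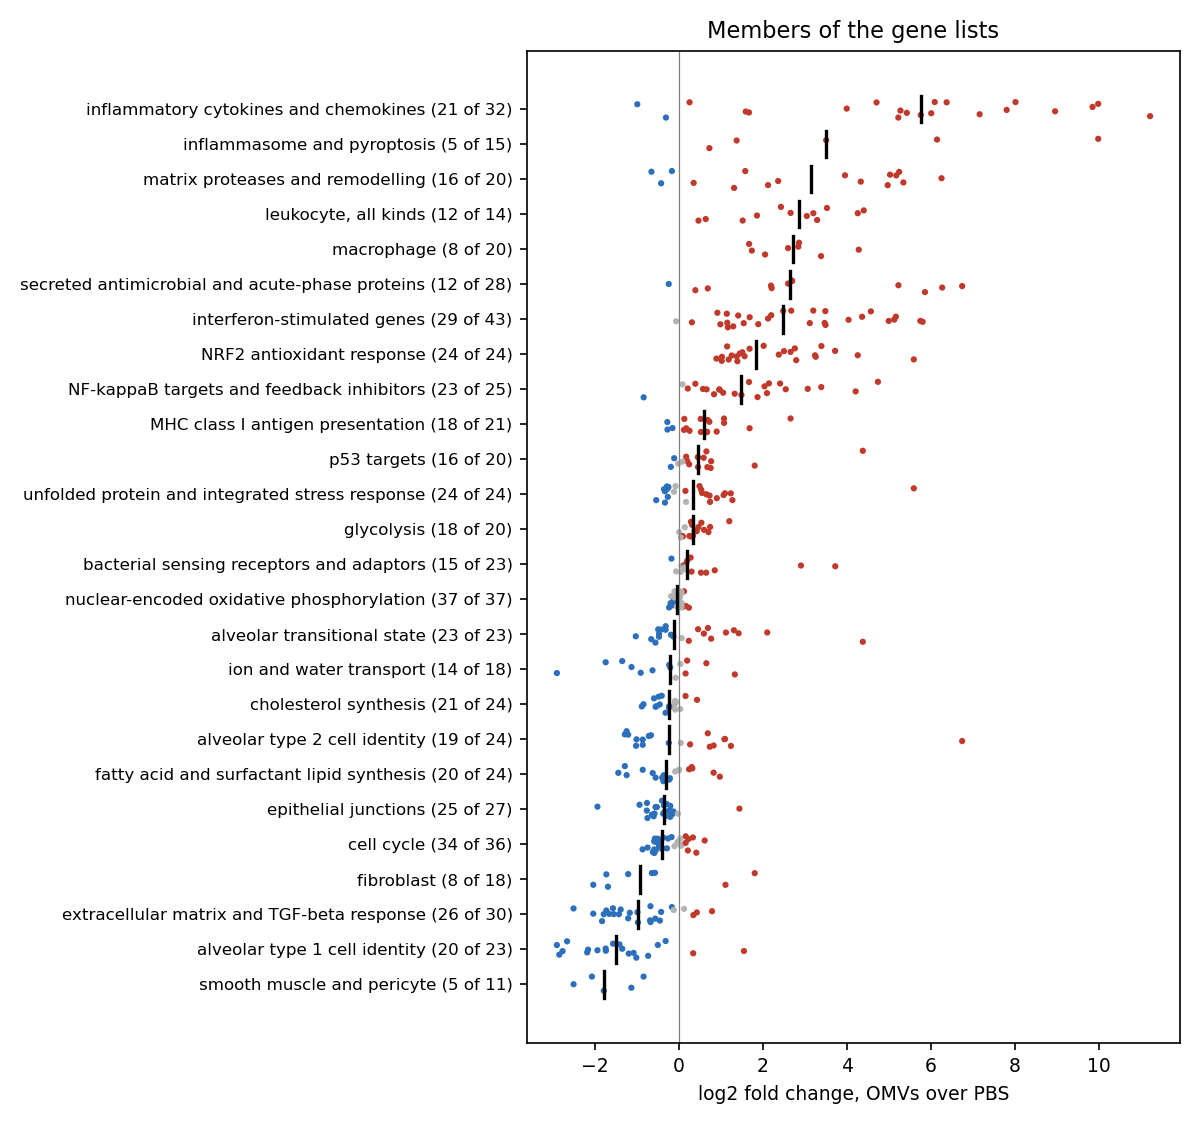
Log2 fold change of OMVs over PBS (x axis) for each measured member of the 26 lists tested, with the measured and total number of members beside each name. Each point is 1 gene, red if risen, blue if fallen and grey if not past the threshold, and black bars are medians, from 5.76 for cytokines and chemokines to -1.78 for smooth muscle and pericyte genes. Points are spread vertically at random.

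The NRF2 antioxidant list, targets of a transcription factor that responds to oxidative and electrophilic stress, rose in all 24 of its members (median 1.85, camera adjusted p = 6.3e-54). Slc7a11, the cystine transporter, was 48.3-fold higher, going from 26.6 ± 1.65 to 1284 ± 64.1 CPM (5.59 ± 0.06). Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was 19.2-fold higher, going from 135 ± 1.77 to 2583 ± 35.9 CPM (4.26 ± 0.03). Pan-leukocyte markers rose beside it (median 2.86). The unfolded protein and integrated stress response list had 13 risen and 8 fallen of 24 members (median 0.33, camera adjusted p = 0.0075, and adjusted p = 0.38 with an estimated correlation). In the subset by PBS level its median turned to -0.16 (adjusted p = 0.978). Slc7a11 is shared with the NRF2 list, and Ddit3, a stress-induced transcription factor, rose by 1.28 ± 0.09, while the chaperone genes Dnajc3 (-0.53 ± 0.04) and Hsp90b1 (-0.35 ± 0.03) fell. Targets of p53 rose in 12 and fell in 2 of 16 measured members (median 0.46, camera adjusted p = 0.00024), with Gdf15 and the kinase gene Plk2 (1.81 ± 0.03) in front and Ei24 (-0.19 ± 0.03) and Ccng1 (-0.11 ± 0.03) fallen. Ccng1 lost its call in limma on log2(FPKM + 1) (adjusted p = 0.0557).

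Glycolysis genes rose, and lipid synthesis and cell cycle genes fell, but none of these calls held with an estimated correlation between genes. Glycolysis genes rose in 15 of 18 measured members and fell in none (median 0.33, camera adjusted p = 0.0086, and adjusted p = 0.18 with an estimated correlation). Slc2a1, a glucose transporter, rose by 1.20 ± 0.04 and Slc16a3, a lactate transporter, by 0.75 ± 0.06. Of 37 nuclear genes of oxidative phosphorylation 3 rose and 7 fell (median -0.04, camera adjusted p = 0.58), the largest changes being 0.24 ± 0.05 for Uqcrq and -0.23 ± 0.04 for Atp5o. The 8 measured mitochondrially encoded genes took 1.93% ± 0.04 of reads with PBS and 1.70% ± 0.05 with OMVs. Fatty acid and surfactant lipid genes fell in 12 and rose in 5 of 20 measured members (median -0.29, camera adjusted p = 0.018, and adjusted p = 0.086 with an estimated correlation), with Scd2, a desaturase, at -1.44 ± 0.03 and Elovl6, an elongase, at 0.98 ± 0.08. Cholesterol synthesis genes fell in 12 and rose in 2 of 21 (median -0.23, camera adjusted p = 0.035, and adjusted p = 0.11 with an estimated correlation). Insig1, a regulator of the pathway, fell (-0.84 ± 0.05), and Hsd17b7 rose (0.44 ± 0.04). This call was lost without PBS replicate 3 (adjusted p = 0.0537) and in the subset of genes with a geometric mean of at least 39.4 CPM (median -0.11, adjusted p = 0.125). Cell cycle genes fell in 22 and rose in 7 of 34 (median -0.39, camera adjusted p = 0.049, and adjusted p = 0.11 with an estimated correlation). The mitotic genes Cdc20 (-0.86 ± 0.07) and Cenpf (-0.74 ± 0.08) fell, and Ccne1, the G1/S cyclin E1 (0.62 ± 0.07), and Pcna, the DNA replication clamp (0.42 ± 0.05), rose. The cell cycle call did not hold without PBS replicate 1 (adjusted p = 0.0504), PBS replicate 2 (0.0542), PBS replicate 3 (0.0665) or OMVs replicate 2 (0.0526). In the subset by mean level the cell cycle median was -0.03 (adjusted p = 0.645). In the libraries of these lists pan-leukocyte markers rose (median 2.86) and fibroblast and smooth muscle markers fell (medians -0.92 and -1.78).

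Matrix genes fell and matrix proteases rose. Extracellular matrix and TGF-beta response genes fell in 21 and rose in 3 of 26 measured members (median -0.97, camera adjusted p = 3.9e-15). Acta2, smooth muscle actin, went from 1015 ± 30.1 to 179 ± 3.47 CPM (-2.50 ± 0.04), and the fibrillar collagen gene Col1a2 from 974 ± 19.2 to 238 ± 3.41 CPM (-2.03 ± 0.03). Zeb2, a transcription factor (0.79 ± 0.06), and Tnc, tenascin C (0.43 ± 0.06), rose. Fibroblast markers, some of them shared with this list, fell in 6 and rose in 2 of 8 measured members of 18 (median -0.92, camera adjusted p = 0.0016). Col1a1 fell (-1.72 ± 0.05), while Dcn, which encodes decorin (1.81 ± 0.05), and Pdgfra, a growth factor receptor (1.11 ± 0.05), rose. All 5 measured smooth muscle and pericyte markers of 11 fell (median -1.78, camera adjusted p = 2.1e-09), Actg2, another smooth muscle actin, by -2.06 ± 0.06 on the log2 scale. Matrix protease and remodelling genes rose in 13 and fell in 3 of 16 measured members of 20 (median 3.16, camera adjusted p = 1.3e-33). The metalloproteinase genes Mmp13 (6.25 ± 0.06) and Mmp10 (5.35 ± 0.06) rose, and Mmp14 (-0.65 ± 0.03) and Timp1, an inhibitor of these enzymes (-0.42 ± 0.04), fell. Mmp13 and Mmp10 had PBS means of 2.685 and 3.683 CPM. These lie under the lowest OMVs mean of 13.92 CPM, so both genes could enter only as rises. The rise of pan-leukocyte markers (median 2.86) stood beside both lists.

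Outside the lists, the largest falls included Ndnf, a secreted neurotrophic factor, which was 8.94-fold lower (785 ± 18.8 to 87.8 ± 3.31 CPM, -3.16 ± 0.04). Egfl6 (-3.06 ± 0.05) and Fbln5, an elastic fibre protein (-2.93 ± 0.06), followed, with the adhesion molecule Mcam (-2.77 ± 0.04) and the aminopeptidase gene Enpep (-2.69 ± 0.05). Fibroblast markers fell in the same libraries (median -0.92).

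Markers of other cell types were measured in every library. Pan-leukocyte markers rose in all 12 measured members of 14 (median 2.86, camera adjusted p = 4.2e-19). Ptprc, which encodes CD45, went from 6.27 ± 0.461 to 51.9 ± 3.95 CPM (3.05 ± 0.08), Lcp2 rose by 4.40 ± 0.13 and Cd53, the most abundant of them with OMVs, reached 129 ± 4.96 CPM (4.26 ± 0.07). Ptprc, Lcp2 and Cd53 had PBS means under the lowest OMVs mean of 13.92 CPM and could enter only as rises. The median and camera p of the pan-leukocyte list are therefore biased towards rises. Macrophage markers rose in all 8 measured members of 20 (median 2.72, camera adjusted p = 1.8e-17), Adgre1, which encodes F4/80, by 4.28 ± 0.12 and Clec7a, which encodes dectin-1, by 3.39 ± 0.08. A further macrophage marker, C1qb, a complement gene held in the FPKM table alone, went the other way, from 4.31 ± 0.343 FPKM with PBS to 0.202 ± 0.091 with OMVs (limma adjusted p = 7.86e-11 on log2(FPKM + 1)). Of 15 neutrophil markers 4 were measured and rose, among them Clec4d (6.44 ± 0.06) and Mmp9 (5.03 ± 0.11), and the 1 measured lymphocyte marker of 17, Il7r, rose by 3.36 ± 0.09. Adgre1, Clec7a, Clec4d, Mmp9, the neutrophil marker Ltf and Il7r had PBS means under the lowest OMVs mean of 13.92 CPM. They could enter only as rises, so their direction says nothing about the unmeasured markers of these cells. Of 11 club and secretory airway markers 4 were measured and rose, led by Hp, haptoglobin (2.20 ± 0.08), and Aldh1a1 (0.85 ± 0.05). Single measured markers were Krt17 of basal cells (12.2 ± 1.27 to 24.5 ± 0.616 CPM, edgeR adjusted p = 4e-08), Eng of endothelial cells (0.43 ± 0.05) and Foxj1 of ciliated cells (-0.40 ± 0.08). Of 3 measured mesothelial markers Msln rose (0.34 ± 0.03) and Cpe (-0.96 ± 0.06) and Krt19 (-0.14 ± 0.03) fell. Hp and Krt17 also had PBS means under 13.92 CPM and could enter only as rises. No erythroid marker was measured.

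**Figure D3:**
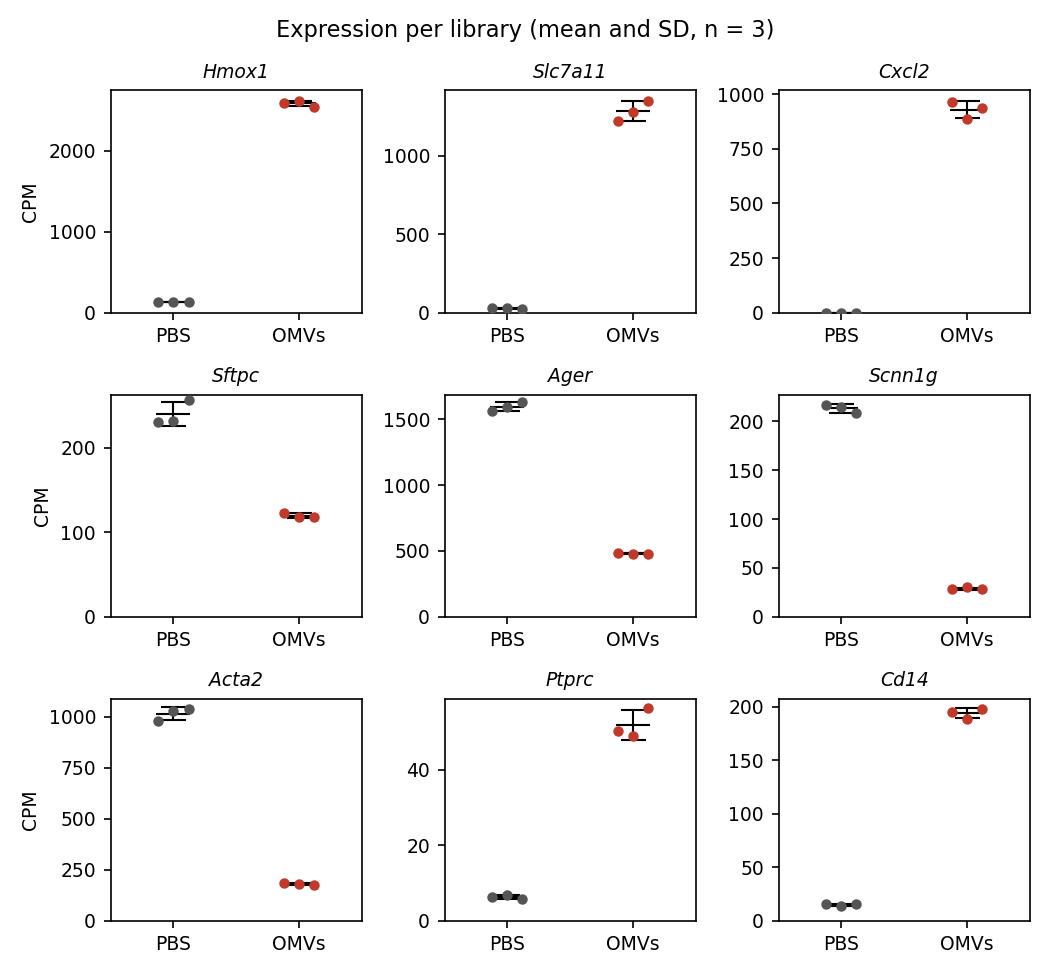
CPM per library of 9 genes with PBS and with OMVs. Points are the 3 libraries of a group, with a horizontal mark at the mean and bars of 1 SD. Axes start at 0. In each panel the groups do not overlap, as for Sftpc with means of 240 and 120 CPM and Ptprc with means of 6.27 and 51.9 CPM.

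In camera 23 of the 26 tested lists were called, and 16 of these held with an estimated correlation between genes. The calls that did not hold are those given above with an estimated correlation. For calls that held, the adjusted p was far larger with it. It went from 1.8e-103 to 0.0011 for cytokines and chemokines, from 6.3e-54 to 0.0064 for NRF2 and from 8.5e-34 to 0.0036 for interferon-stimulated genes. Adjusted over the list alone, the number of changed genes in each list was the same as over all genes, except for bacterial sensing (11 in place of 10), oxidative phosphorylation (8 in place of 10) and the unfolded protein and integrated stress response (22 in place of 21). The 109 genes chosen by the rule all passed the edgeR test. Their largest adjusted p was 0.0327, for Mvd of the cholesterol list (0.16 ± 0.06), whose call was lost in 7 of the other settings.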

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

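The sign test over pan-leukocyte markers, the test of their spread, the comparison of type 1 with junction genes and the bound on the share of abundant genes were chosen after the values had been seen. The other tests had their outcomes written down first.

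A signal appeared in data outside the comparison, in the 262 genes of the FPKM table that the count tables did not hold. With a mean of at least 1 FPKM with OMVs, at least 8 times the PBS mean and no overlap between the groups, 6 genes stood out. Csf2, a growth factor for myeloid cells, had 8.74 ± 0.586 FPKM with OMVs (SD, n = 3) and 0.363 ± 0.394 with PBS. Rgs1, a regulator of G protein signalling, had 7.29 ± 0.528 against 0.321 ± 0.122. Pdcd1, which encodes the inhibitory receptor PD-1, had 3.06 ± 0.244 against 0.180 ± 0.172. Il10, an anti-inflammatory cytokine, had 2.61 ± 0.239 and was listed at 0 in 2 of the 3 PBS libraries. Gpr18 had 1.61 ± 0.288 against 0.083 ± 0.034, and Kit, a stem cell factor receptor, 1.23 ± 0.191 against 0.150 ± 0.063. In limma on log2(FPKM + 1) the adjusted p ranged from 2.31e-11 for Rgs1 to 1.9e-07 for Kit. By the mirrored rule, with PBS higher, C1qb (4.31 ± 0.343 with PBS and 0.202 ± 0.091 with OMVs) and Sh3bgr (33.7 ± 2.07 with PBS and 4.11 ± 0.107 with OMVs, limma adjusted p = 6.21e-13) stood out. Over the 262 genes, 107 passed the filter on low FPKM, of which 31 rose and 42 fell.

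Leukocyte and macrophage markers were higher with OMVs. Their rise could reflect the fact that genes low in the OMVs libraries were not measured. Counting every unmeasured member as fallen, 12 of 14 pan-leukocyte genes still rose, so the unmeasured members do not account for the rise of most of that list. The two-sided exact sign test gave p = 0.013. It takes genes as independent, and markers of 1 cell class can move together, so this p is not used as evidence. For macrophage genes no such statement can be made: 8 of 20 were in the count tables, 0 of them had a PBS level high enough for a 4-fold fall to be seen, and C1qb, in the FPKM table alone, was lower with OMVs (0.202 against 4.31 FPKM). For the pan-leukocyte genes, more leukocytes of one mix and state stay open as well. That alone would not lower C1qb, but C1qb is a single gene and does not settle the question for the others. The log2 fold changes of pan-leukocyte genes had an SD of 1.28 against a median standard error of 0.07, but genes that other cells already express would rise less, so this spread decides nothing. Leukocytes of changed mix or state, or expression by the epithelial cells as a response to OMVs, stay open and were not tested.

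Alveolar type 1 genes were lower with OMVs. A lower share of epithelial RNA would lower epithelial genes alike. With genes shared by both lists left out, the type 1 median lay 1.07 log2 units below the junction median (difference -1.07, two-sided permutation test over genes, taken as independent, p = 3e-05). Junction genes that other cells also express would fall less, so this difference alone does not decide the question. The fixed epithelial genes Epcam (-0.20 ± 0.04) and Cdh1 (-0.74 ± 0.03) fell by less than the type 1 median. Gene length may bias counts, yet with a length trend removed the type 1 median was -1.48, with an upper quartile of -0.93. A different balance of type 1 and type 2 cells and a change within type 1 cells cannot be separated by these libraries, and neither was tested.

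The NRF2 list was higher with OMVs. A few abundant genes giving up counts with OMVs could raise all others. The 50 most abundant genes took 12.6% to 12.7% of reads with PBS and 11.8% to 12.1% with OMVs, which can raise other genes by at most 0.015 on the log2 scale against a list median of 1.85. A refit without these genes, run first, could not have come out otherwise and is not used as evidence. A contribution of other cell types, with pan-leukocyte markers at a median of 2.86, and a response of the cells to OMVs both stay open and were not tested.

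Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, gave as many changed genes, 5561, and the highest of the others gave 0. With 10 splits the share cannot go under 0.1, so these splits are too few to judge chance.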

How the results depend on the processing

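The subsets by level and the length correction were chosen after seeing the data. Over the settings that kept all or nearly all genes and no fold limit, 15 in number, changed genes ranged from 4683 (at an adjusted p under 0.01) to 5897 (length trend removed), and leaving out each library gave 5084 to 5724. The even split of directions shifted to rises in limma on FPKM, with 3191 risen and 2500 fallen on log2(FPKM + 1), 3178 and 2481 on log2(FPKM + 0.1), and 3195 and 2513 with no filter. The first component held 97.0% of the variance on log2(FPKM + 1) and 99.3% over the 500 most variable genes. Both other filters on low counts removed no gene and tested nothing. Same-numbered samples did not deviate together (correlations of -0.167, -0.063 and -0.365 across genes). The replicate block gave 5169 changed genes (2598 risen, 2571 fallen), 5156 of them shared with the fit without it, and ended no list call and, of the named genes, only that of Mvd.

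With a 2-fold limit 689 genes were called (455 risen, 234 fallen). Refitted on genes of a geometric mean of at least 39.4 CPM, 3606 changed (1815 risen, 1791 fallen). There type 2 identity gained a downward call (median -0.83, adjusted p = 0.00528) and transitional state an upward one despite its negative median (-0.10, 0.0165). Cholesterol synthesis (-0.11, 0.125) and cell cycle (-0.03, 0.645) lost theirs. An earlier form of this subset took the 2000 genes whose PBS level was at least 8 times the lowest OMVs mean. It was replaced, after its result was seen, because choosing genes by 1 group favours falls. By the calls over all genes it held 563 risen and 983 fallen, 36.4% risen. Refitted and rescaled on its own genes, it gave 1560 (786 risen, 774 fallen). In it type 2 identity gained a call (-0.75), cholesterol synthesis lost its own (-0.29), and the unfolded protein and integrated stress response turned to a median of -0.16 (adjusted p = 0.978). Fewer genes were tested in both subsets. Beyond that, the cause was not tested.

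An estimated correlation ended the calls of bacterial sensing (median 0.20), MHC class I (0.60), fatty acid (-0.29), cholesterol (-0.23), glycolysis (0.33), unfolded protein (0.33) and cell cycle (-0.39) lists, with medians unaltered by construction. Fry called the transitional list in the upward direction, although its median was -0.12. Without the length trend the cell cycle list had a median of -0.39 and an adjusted p of 0.0594, and 5897 genes changed (3117 risen, 2780 fallen), 5316 of them shared. Leaving out 1 library gave medians from -0.44 to -0.36 for cell cycle (called in 2 of 6), -0.24 to -0.21 for cholesterol (5 of 6) and -0.14 to -0.10 for the transitional list (1 of 6). Of the 109 named genes, Mvd, Lyz1, Ripk2, Ndufb10 and Ccng1 lost their call in at least 1 setting, and none reversed. Genes with few reads with OMVs were not analysed here, and in simulated counts 84.7% of the smallest changes were recovered.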

Other observations

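The genes and lists in this part were chosen after the data had been seen, apart from the fixed marker lists, and the outcomes of the tests of aryl hydrocarbon receptor and YAP targets were written down before those tests were run.

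Genes of iron and heme handling, glutathione and prostaglandin synthesis are given as values, since as groups they were not tested. The ferritin subunit genes Fth1 and Ftl1 went from 1319 ± 67.5 to 6880 ± 162 CPM and from 2705 ± 120 to 6170 ± 189 CPM (SD, n = 3), log2 fold changes of 2.38 ± 0.04 and 1.19 ± 0.03. Blvrb, a biliverdin reductase, rose by 2.16 ± 0.05, and Flvcr2, a membrane transporter, fell (-2.27 ± 0.06). Of 14 measured iron handling genes 10 rose and 3 fell. Gclc and Gclm, the subunits of the enzyme that starts glutathione synthesis, rose by 3.24 ± 0.03 and 2.66 ± 0.04, and 12 of 14 glutathione and thioredoxin genes rose, while Gpx4, which reduces lipid peroxides, was slightly lower (-0.17 ± 0.04). In the prostaglandin pathway Ptgs2, the inducible cyclooxygenase, went from 680 ± 11.8 to 3623 ± 56.5 CPM (2.41 ± 0.03) and Ptges, a prostaglandin E synthase, went from 31.0 ± 0.396 to 248 ± 2.10 CPM. Pla2g7 and Pla2g4a, phospholipases, rose by 5.63 ± 0.07 and 1.38 ± 0.04. Slco2a1, a prostaglandin transporter, fell from 572 ± 29.5 to 99.0 ± 3.43 CPM (-2.53 ± 0.04), and Ptgs1 fell (-0.79 ± 0.03). Of 9 measured prostaglandin genes 7 rose and 2 fell. In the same libraries pan-leukocyte markers rose (median 2.86) and fibroblast markers fell (median -0.92). Fth1, Ftl1, Gclc and Gclm are on the NRF2 list, as is Hmox1 of the iron genes. So are Slc7a11, Gsr, Txnrd1, Srxn1, Prdx1 and G6pdx of the glutathione and thioredoxin genes. Hp and Lcn2 of the iron genes are on the antimicrobial list, and Ptgs2 is on the NF-kappaB list. These values and counts therefore do not add to those lists.

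Of the fixed marker lists for other cell types, the FPKM table alone held 4 lymphocyte genes, 1 macrophage gene and 1 smooth muscle gene. The lymphocyte genes were higher with OMVs, with no overlap between the groups. Ltb had 8.92 ± 1.12 FPKM with OMVs and 1.34 ± 0.184 with PBS, Cd3e 1.80 ± 0.446 against 0.322 ± 0.046, Cd2 1.71 ± 0.225 against 0.298 ± 0.079, and Cd4, under the filter on low FPKM, 0.754 against 0.242. Cd27, a lymphocyte gene on none of the lists and also under that filter, had 0.888 ± 0.208 against 0.815 ± 0.242. It overlapped between the groups (adjusted p = 0.614 in limma on log2(FPKM + 1) with no filter). The macrophage gene C1qb was lower with OMVs, with 0.202 ± 0.091 against 4.31 ± 0.343, as was the smooth muscle gene Des, with 2.10 against 5.43. With the filter on low FPKM, the adjusted p in limma on log2(FPKM + 1) was 1.07e-06 for Cd3e and 7.86e-11 for C1qb.

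Within each group the libraries differed along gene length. Spearman's rho across genes between a library's deviation from its group mean and gene length was 0.51, 0.12 and -0.51 for PBS replicates 1 to 3 and -0.34, -0.22 and 0.49 for OMVs replicates 1 to 3. Between the groups, rho of the log2 fold change with length was -0.132. Genes are not independent replicates, so no p is given. With the trend removed the coefficient of variation went from 4.9% to 4.2%.

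Cyp1a1 and Aldh3a1, enzymes of xenobiotic metabolism, were among the largest rises, with log2 fold changes of 5.33 ± 0.08 and 5.69 ± 0.08. The hypothesis that targets of the aryl hydrocarbon receptor rose as a group was tested on other members of a target list. Of 15 measured, 10 rose and 4 fell, with a median of 0.85 and a camera p of 7.4e-05, or p = 0.013 with an estimated correlation. Tiparp (2.68 ± 0.04), Cyp1b1 (2.30 ± 0.03) and Ahrr, the receptor's repressor (1.96 ± 0.15), rose, while Tgm2 (-0.94 ± 0.03) and Socs2 (-1.29 ± 0.04) fell. Pan-leukocyte and macrophage markers rose (medians 2.86 and 2.72) and fibroblast and smooth muscle markers fell (-0.92 and -1.78) in the same libraries. The rise is consistent with activity of the receptor with OMVs, as a hypothesis, in cells that these libraries do not identify. Nfe2l2, which encodes NRF2, is on the list, so the lists are not independent.

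Ccn1 and Ccn2, matricellular genes, fell (-0.97 ± 0.03 and -1.65 ± 0.03). The hypothesis that targets of the transcriptional regulator YAP fell as a group was tested on other members. Of 22 measured, 14 fell and 3 rose, with a median of -0.37. The camera p was 0.041 with the preset correlation and 0.28 with an estimated one, and the test had asked for p under 0.05 with both, so a fall of the targets as a group was not borne out.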
